A study of Rattus norvegicus with 11 samples.

How the data were processed

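RNA from the hippocampi of male albino Wistar rats aged 12 weeks was measured on 11 two-channel Agilent arrays, 1 pool of 3 rats per array. Per the labels' protocols, total RNA was amplified and labelled with a low-input kit, with Cy5 for the hippocampal pool and Cy3 for a common reference on every array. The reference was a pool of hippocampal, thalamic and cortical tissue from rats of all 3 groups. The groups were rats given high-frequency stimulation of the ventrolateral thalamus (deep brain stimulation, DBS; 1 hour a day for 14 days; 4 arrays), sham-operated rats (4 arrays) and naive rats (3 arrays). The labels call these biological replicates, so the spread between arrays of a group holds both the difference between pools and the technical error.

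The deposited values are 1 log ratio for each of 45220 numbered array features on each array, taken here as log2. The log base is not given in the sources used here; the values lie between -4.59 and 4.52, and a base of 10 would make the outer values implausibly large for 1 scan. The deposited log2 values had no missing entry, and the median of each array was -0.00589 to 0.00535, which means that the deposited values had been centred near 0. The background correction, the normalization, the filtering of spots and the slide and scan dates are not given in the sources used here. No batch could therefore be tested, and no signal over background could be computed. The number of arrays limits the precision.

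A positive value is taken to mean more RNA in the hippocampal pool than in the reference, from the order in the labels' descriptions and the dyes. The direction could not be checked on marker genes. All 55 pairs of arrays correlated positively, between 0.732 and 0.932 over all features, so all arrays run the same way. If the deposited ratio were the reverse, every sign given here would turn and the counts of higher and lower features would change places, while total counts and sizes would stay.

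Gene names were not used. A platform annotation made available for this work lists 24511 of the 45220 features, of which 24461 carry 1 gene symbol and 50 carry several, and leaves 20709 unlisted. Before any gene was named, the annotation was checked on the values: features that share a symbol should have similar log ratios. For the 3544 symbols with exactly 2 features the correlation of the mean log ratios across pairs was 0.0107, and 1000 random reassignments of values to features reached up to 0.0494 (one-sided permutation p = 0.25). The 2540 accessions with 2 features gave 0.0073. The numbered rows of the value table therefore could not be tied to the annotation's genes. Results are given by array feature, at most 2 features are identified in each direction of the main comparison, and the 35 gene lists fixed before the data were examined were not tested, apart from 6 lists of brain regions that served as a check of the names.

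Group means were fitted for all features over all 11 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes at default settings), so that the 3 groups shared an estimate of the spread. Where both groups compared varied more than the remaining group, the SE of that comparison can be too small. The comparisons were DBS against sham, sham against naive and DBS against naive, each two-sided, together with a moderated F test for any difference among the groups. P-values were adjusted by the Benjamini-Hochberg method over the 45220 features, and features with an adjusted p under 0.05 are called changed. The plan made before the data were examined averaged features by gene symbol and left out control features, with single features as the fallback where no gene names could be had. The fallback became the main setting because the names failed the check, and the averaged version is an alternative. Control features could not be told from others and stayed in; features of control type that do not differ between groups add to the number tested. The identified features are those with the largest change of each sign in DBS against sham among changed features whose arrays of both groups do not overlap.

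The fit was tested on simulated data with the moderated (eBayes) spread of the real features, drawn independently for each feature and array. Deviations that features share were not simulated, so the rates below can be better than those for the real data. For DBS against sham, with 45220 features of which 50 were changed by each fold size, it recovered 96% of 1.5-fold, 100% of 2-fold and 100% of 4-fold increases, and it made 10 calls among the unchanged features.

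Alternatives fixed before the data were examined were centring on the median, quantile normalization between arrays, averaging by the annotation's symbols, only features with 1 symbol, leaving out the features of lowest SD, robust eBayes, array weights, only the groups compared, the replicate number as a block, and leaving out each array in turn. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the check of the names, and matplotlib 3.10.9 for the plots. Features were called near-identical when their log ratios lay within a Euclidean distance of 0.6 of each other over the 11 arrays in the count of distinct profiles, with average linkage. A profile can also group features that are merely alike, so the number of profiles can be below the number of distinct probes.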

Results

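Hippocampal RNA was compared between rats that received deep brain stimulation (DBS), sham-operated rats and naive rats, in 11 arrays against a common reference of pooled brain tissue. DBS means electrical stimulation through an electrode, here at high frequency in the ventrolateral thalamus, a relay nucleus for motor signals. Each array held a pool of 3 rats, with 12 rats in the DBS group, 12 in the sham group and 9 in the naive group. Every array gave a log2 ratio for all 45220 features. The SD of the log2 ratios over the features of an array was 0.362 to 0.387, and the median SD of a feature between arrays of a group was 0.0852.

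The arrays separated by group, in the order naive, sham, DBS. The first principal component held 37.9% of the variance. Scores on it averaged 21.7 ± 5.92 for DBS (SD, n = 4), -4.6 ± 4.6 for sham (SD, n = 4) and -22.8 ± 2.14 for naive (SD, n = 3). Each of the 3 pairs of groups was separated without overlap (exact two-sided permutation p = 0.0286 for each, 0.0286 after adjustment over the 3 tests, the smallest the design allows). Correlations over all features averaged 0.927 between naive arrays, 0.893 between sham arrays and 0.875 between DBS arrays. They were 0.837 between DBS and sham, 0.878 between naive and sham, and 0.775 between DBS and naive. These correlations are across features, which are not independent replicates.

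**Figure D1:**
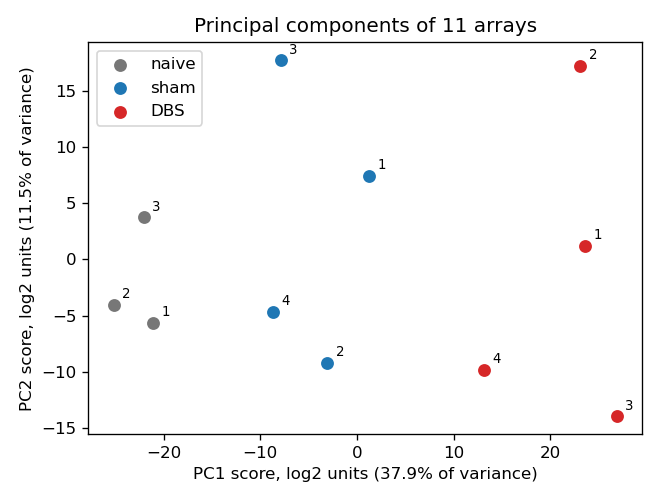
Scores of the 11 arrays on the first (x axis) and second (y axis) principal components of the log2 ratios, in log2 units; each point is 1 array, coloured by group and marked with its replicate number. The 3 groups do not overlap on the first component, which holds 37.9% of the variance, while the second holds 11.5%.

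The comparison of DBS with sham asks what stimulation adds to the operation. Of 45220 features, 1275 (2.82%) changed, 877 higher and 398 lower in DBS (limma, adjusted p under 0.05). Most changes were small: the median size was 0.35 on the log2 scale (quartiles 0.26 and 0.53), and 1019 of the changed features differed by less than 1.5-fold. At least 2-fold changes were found for 67 features, 58 higher and 9 lower. Many of these were copies of each other, and the 67 features had 34 distinct profiles over the arrays. Arrays of both groups did not overlap for 9.42% of all features, where chance gives 2.86%. The count fell to 816 without DBS replicate 1, to 814 without sham replicate 3, to 784 without sham replicate 4 and to 806 with only DBS and sham arrays in the fit. The lower calls were the less stable part in several fits: they numbered 223 and 262 without DBS replicates 1 and 3, 187, 262, 233 and 218 without sham replicates 1, 2, 3 and 4, and 200 with only DBS and sham arrays, while the higher calls numbered at least 566 in these fits. Without DBS replicate 2 the reverse held, with 750 higher and 410 lower. Centring on the median gave 865 higher and 416 lower, and robust eBayes gave 862 and 403.

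Among the features at least 2-fold higher in DBS than in sham were 3 sets of 10 features each whose values were nearly equal on every array, with a mean SD between features of a set of 0.0398 to 0.0488. Such sets behave as repeated spots of a single probe; they were picked out after the values were seen. In the set with the lowest adjusted p-values, the mean log2 ratio was 1.30 ± 0.50 in DBS (SD, n = 4), 0.05 ± 0.26 in sham (SD, n = 4) and -0.24 ± 0.10 in naive (SD, n = 3). The difference between DBS and sham was 1.25 (SE 0.20, limma adjusted p 0.00345 to 0.0118 over its features), a 2.38-fold higher level without overlap between the arrays. In the next set the means were 1.62 ± 0.77 in DBS (SD, n = 4), 0.11 ± 0.48 in sham (SD, n = 4) and -0.52 ± 0.05 in naive (SD, n = 3), a 2.85-fold difference between DBS and sham (log2 1.51, SE 0.32, limma adjusted p 0.0161 to 0.0285) with overlap of DBS replicate 4 and sham replicate 3. All 10 of its features lost the call with robust eBayes, without DBS replicate 1 and without sham replicate 4; 1 feature kept it without DBS replicate 2 and 1 without sham replicate 2, and 4 kept it without DBS replicate 3.

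The remaining set had the widest range of the 3. Its mean log2 ratio was 1.61 ± 0.97 in DBS (SD, n = 4), -0.77 ± 1.04 in sham (SD, n = 4) and -3.08 ± 0.05 in naive (SD, n = 3). DBS was 5.19-fold above sham (log2 2.38, SE 0.50, limma adjusted p 0.0183 to 0.0263), with overlap of DBS replicate 4 at 0.27 and sham replicate 1 at 0.62, and 25.8-fold above naive (log2 4.69, SE 0.54, limma adjusted p 0.000109 to 0.000165). The difference of 2.31 between sham and naive did not pass the threshold for any of its features, although the arrays did not overlap. The set mean ran from -1.68 to 0.62 in sham and from -3.13 to -3.03 in naive. For DBS against sham, all features of this set lost the call with robust eBayes and without each of DBS replicates 1, 2 and 3 and sham replicates 3 and 4, and 6 kept it without sham replicate 2. In all 3 sets the naive arrays varied least, while the fit shares its estimate of the spread over the groups. The SEs for DBS against sham can therefore be too small.

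Among changed features without overlap between DBS and sham arrays, the largest increases were at features 34775 and 25436, members of a set of 9 near-identical features. These were the 2 of the 9 that passed the threshold; the other 7 were 1.69 to 1.84 higher in DBS than in sham, also without overlap, and did not pass (limma adjusted p 0.0538 to 0.0716). Feature 34775 stood at 1.94 ± 1.17 in DBS (SD, n = 4), 0.13 ± 0.32 in sham (SD, n = 4) and -0.68 ± 0.22 in naive (SD, n = 3), which is 1.81 higher in DBS than in sham (SE 0.43, limma adjusted p = 0.0416). Feature 25436 was 1.78 higher (SE 0.42, limma adjusted p = 0.0442). Both features varied most in DBS and least in naive, and the fit shares its estimate of the spread, so these SEs can be too small. Both calls are fragile. Feature 34775 kept its call in 6 of 16 alternatives and feature 25436 in 5, and the highest adjusted p, with robust eBayes in limma, was 0.139 and 0.142. Leaving out DBS replicate 1 or any single sham or naive array ended both calls, and leaving out DBS replicate 2 also ended that of feature 25436, with limma adjusted p between 0.0536 and 0.125 in these fits.

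The largest decreases among changed features without overlap were at features 18798 and 33617, a near-identical pair that stood out in the sham group. Feature 33617 had a mean log2 ratio of -1.98 ± 0.30 in DBS (SD, n = 4), -0.26 ± 0.44 in sham (SD, n = 4) and -2.78 ± 0.21 in naive (SD, n = 3). It was lower in DBS than in sham by a log2 difference of -1.72 (SE 0.20, limma adjusted p = 0.00119), and higher in sham than in naive by 2.52 (limma adjusted p = 0.0005). Feature 18798 differed by -1.74 between DBS and sham (SE 0.25, limma adjusted p = 0.00272) and by 2.52 between sham and naive (limma adjusted p = 0.00153). Both kept their call for DBS against sham in all 16 alternatives that were run for them. Between DBS and naive, feature 33617 was 0.80 higher (limma adjusted p = 0.0366) and feature 18798 was 0.78 higher, which did not pass the threshold (limma adjusted p = 0.105).

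**Figure D2:**
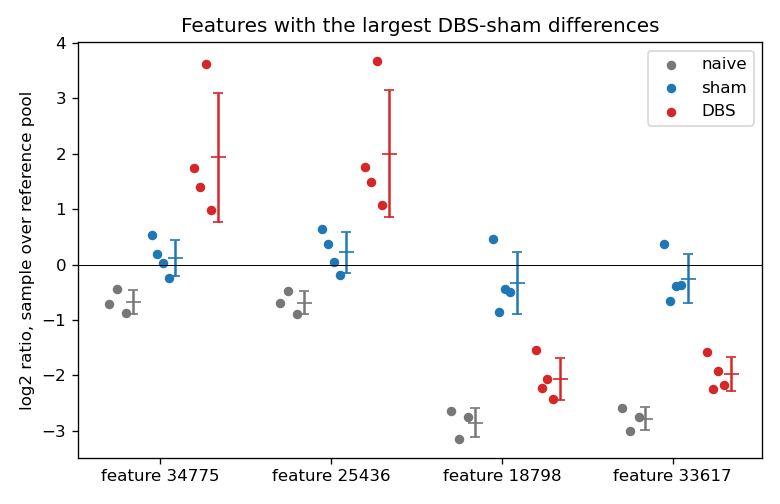
Log2 ratio over the reference pool (y axis) of the 4 identified features (x axis) on each array; points are arrays, and the dash with bars beside them is the mean ± SD of naive (n = 3), sham (n = 4) and DBS (n = 4). Features 34775 and 25436 are highest in DBS with a wide spread, and features 18798 and 33617 are highest in sham, at -0.33 and -0.26.

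The comparison of sham with naive asks what the operation does without stimulation. It changed 421 features (0.931%), 332 higher and 89 lower in sham (limma, adjusted p under 0.05), with a median size of 0.50. The 15 features changed by at least 2-fold were all higher in sham and had 13 distinct profiles; besides the pair 18798 and 33617 they held another pair at -0.21 ± 0.47 in sham (SD, n = 4) and -2.14 ± 0.12 in naive (SD, n = 3). Arrays did not overlap for 13.1% of features, where chance gives 5.71%. The count depended on single arrays: it was 127, 165 and 171 without sham replicates 1, 2 and 4, and 109, 87 and 87 without naive replicates 1, 2 and 3. Among these fits the higher calls ranged from 61 to 145 and the lower calls from 9 to 38. The total rose to 760 with array weights.

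The comparison of DBS with naive covers the operation and the stimulation together. It changed 3694 features (8.17%), 2081 higher and 1613 lower in DBS (limma, adjusted p under 0.05), with a median size of 0.34 and a range of log2 differences from -2.35 to 4.74. At least 2-fold changes were nearly all increases, 259 higher and 13 lower, in 89 distinct profiles. These profiles do not hold copies alone. The largest grouped 32 features with a mean SD between features of 0.113, against 0.0458 in the 10-feature set of widest range. The changes were concentrated: the 100 features with the largest differences held 28.7% of the sum of squared differences over all features, and the top 1000 held 61.7%. Part of this comes from copies, which were not merged. The 10-feature set of widest range, 4.69 higher in DBS than in naive, counts 10 times. Arrays did not overlap for 20.1% of features, where chance gives 5.71%. The count was 2083 without naive replicate 2 (1410 higher, 673 lower) and 2339 without naive replicate 3 (1513 higher, 826 lower), so the share of higher calls moved from 56.3% to 67.7% and 64.7%. With only DBS and naive arrays in the fit 1832 were higher and 1061 lower.

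Across the 3 groups, the F test called 2797 features (limma, adjusted p under 0.05; 1767 without naive replicate 2 and 1841 without naive replicate 3). The sham mean lay between the naive and DBS means for 2393 of them (85.6%), in 1550 rising from naive to DBS and in 843 falling. It was the highest of the 3 for 204 and the lowest for 200. Simulated data without effects gave a sham mean in between for 34.8% of the same number of features with the smallest F test p. With the measured DBS and naive means, the simulated share was 50.3% with sham set at the naive level and 49.97% with sham set at the DBS level. Among the 3694 features that differed between DBS and naive, the sham mean lay between the other means for 93.6%. Its median position was 0.45 on a scale from 0 at the naive mean to 1 at the DBS mean (quartiles 0.29 and 0.61), and each sham array had a median position between 0.33 and 0.52. Choosing features for a wide gap between DBS and naive draws the sham mean into that gap by itself. In simulations run after this result was seen, data without effects gave 75.5% in between and a median position of 0.57. With the measured DBS and naive means, sham set at the naive level gave 64.4% and 0.06, and sham set at the DBS level gave 61.5% and 0.95. All these simulations took the same number of features with the smallest p, whether or not they passed the threshold. The position of 0.45 alone therefore does not part an intermediate sham level from the no-effect case. It lay far from the 0.06 and 0.95 simulated with sham at the naive or the DBS level. Estimated over all features with the noise removed, the position was 0.415.

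The difference of DBS from sham and that of sham from naive tended to go in the same direction across features, with copies counted separately. Both use the sham arrays, which alone drives their correlation down: it was 0.179 over all features, against -0.462 in simulated data without effects. The covariance was 0.00334 against a simulated -0.00368, a difference of 0.00702 that estimates the shared part. With the sham arrays split, so that each difference used other arrays, the correlation averaged 0.305 over the 6 ways to split them (0.182 to 0.391). It is a correlation across features, which are not independent replicates. Copies of a probe were not merged, so sets of repeated features weigh more than single ones in these correlations and covariances. The 10-feature set of widest range, at 2.38 for DBS against sham and 2.31 for sham against naive, counts 10 times. Of the features changed in DBS against sham and in sham against naive, 175 changed the same way in both, where independent lists give 7.22, and 8 changed in opposite ways, where independent lists give 4.65. Simulated data without effects gave 0 in both cases, but such data hold almost no calls, so that value says nothing about agreement between the comparisons. With split sham arrays 5 to 208 features changed the same way in both and 4 to 6 in opposite ways.

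**Figure D3:**
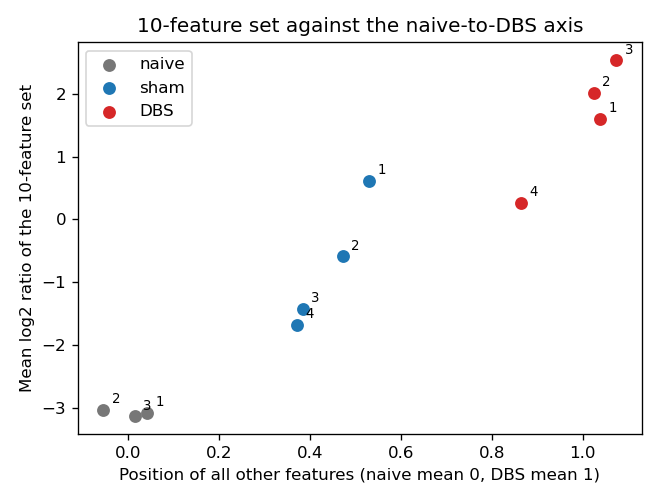
Mean log2 ratio of the 10-feature set with the widest range (y axis) against the position of all other features on a scale from 0 at the naive mean to 1 at the DBS mean (x axis); each point is 1 array with its replicate number. Naive arrays lie together near -3.08, while the set runs from -1.68 to 0.62 in sham arrays and from 0.27 to 2.54 in DBS arrays.

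The gene names of the platform annotation did not match these features. In 214 sets of at least 10 features that the annotation gives the same accession, the median SD of the mean log2 ratio between features of a set was 0.244, and it was 0.251 in random sets of the same sizes. The values do hold sets of repeated features. Features with a mean log2 ratio above 0.9 or below -0.9 were linked where they lay within a distance of 0.3 of each other over the arrays. Only sets with a low SD between features, averaged over the arrays, were kept. This SD was 0.0368 to 0.0627 in the 11 sets of 9 to 12 features. On the measure used for the annotation's sets it was 0.0164 to 0.0427. These low values follow from how the sets were picked. Of the 111 features in these 11 sets the annotation lists 60, and within each set every listed feature has a different accession. Under the annotation's names, the array medians of the region lists averaged -0.051 for dentate granule cell genes, -0.034 for CA1 and subiculum, 0.01 for CA3 and CA2, -0.047 for thalamus, -0.011 for neocortex and -0.028 for striatum. The hippocampal lists minus the thalamic list gave 0.022 ± 0.034 (SD, n = 11 arrays) and was above 0 on 8 of 11 arrays. Against 10000 random lists of the same sizes, drawn after these values were seen, the region lists lay between percentiles 6.11 and 67.6 (smallest two-sided permutation p = 0.121, 0.648 after adjustment over the 6 lists), and the difference of the lists at percentile 73.5 (two-sided permutation p = 0.526). The dentate list was below 0 on all 11 arrays, at percentile 12.3 of random lists.

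**Figure D4:**
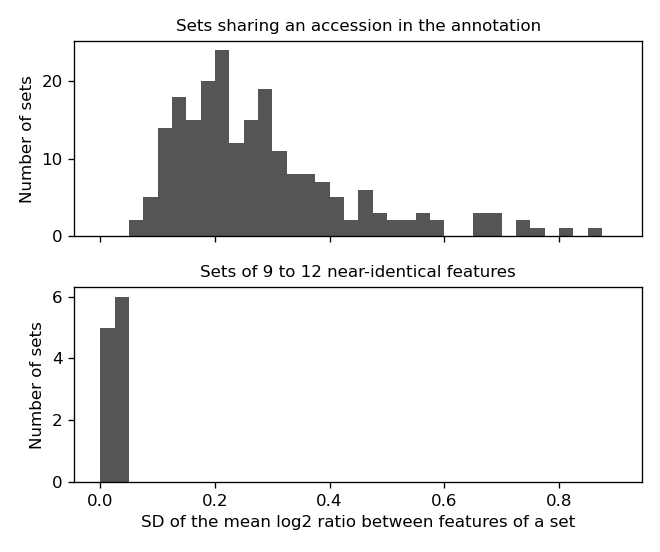
Number of sets (y axis) by the SD of the mean log2 ratio between the features of a set (x axis, log2 units), for the 214 sets that share an accession in the annotation (top) and the 11 sets of near-identical features in the values (bottom). The former have a median SD of 0.244. The latter were picked for their closeness, so their low SD follows from that choice.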

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

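The alternatives were fixed before the data were examined, except those for the 10-feature sets and the SD filter for the 4 identified features, which were added after seeing the data. No count or identified feature turned its direction. Counts of changed features stayed within 1.5 times of the main value for centring, quantile normalization, the SD filter and robust eBayes in all 3 comparisons and the F test. With only features listed under 1 symbol, which tests fewer features, the counts were 722 for DBS against sham, 264 for sham against naive, 2085 for DBS against naive and 1551 for the F test. Averaging by symbol, which also tests fewer rows, gave 945 for DBS against sham, 273 for sham against naive, 2910 for DBS against naive and 2175 for the F test. For sham against naive, array weights gave 760, and fitting only the groups compared gave 806 for DBS against sham; the cause of the last pair was not tested. Leaving out single arrays gave 784 to 1297 for DBS against sham, 87 to 575 for sham against naive, 2083 to 3717 for DBS against naive and 1767 to 2685 for the F test. It gave 0.214 to 0.322 for the correlation of both differences across features, the lowest without sham replicate 3, and 0.017 to 0.028 for the hippocampal minus thalamic lists.

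Arrays with the same replicate number did not deviate together. The correlations of their deviations ran from -0.122 to 0.15, and 1 of 4 DBS arrays deviated most like the sham array of its own number. With the replicate number as a block the counts were 892 for DBS against sham, 319 for sham against naive, 2807 for DBS against naive and 1964 for the F test, with lower calls numbering 213, 36 and 1024 in the 3 comparisons. Features 34775 and 25436 then had limma adjusted p of 0.0516 and 0.0558, within ranges of 0.00647 to 0.139 and 0.00778 to 0.142 over their alternatives. Tests of gene lists and their alternatives were not run because the names failed the check, and the alternative for missing values had nothing to act on. Signal over background, which limits dim features, could not be assessed from log ratios alone.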

Other observations

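All tests in this part were chosen after the results they concern had been seen. Other splits of the same arrays gave fewer changed features than the real groups. For DBS against sham, 1 of 35 splits, the real one, reached 1275, and the highest other count was 12. For sham against naive it was 1 of 35 with 421, the highest other count being 139. For DBS against naive it was 1 of 35 with 3694, the highest other being 940, and for any difference among the 3 groups 1 of 100 with 2797, the highest other being 530. The real groups thus gave the highest count each time, which makes chance assignment of arrays unlikely for these 4 counts. It is not excluded, since with 35 splits no share below 1 of 35 can be reached. A batch that followed the groups would give the same outcome.

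The first pattern is the graded shift from naive over sham to DBS. A compression of the log ratios that differs between the groups is argued against, since it would move the changed features all away from 0 or all towards it. Of the 3694 features changed between DBS and naive, 43.7% moved away from 0 (36.2% to 50.4% by single sham arrays). Sets of 13 or more near-identical features are called control-like here for their size alone, and it is not known whether they are control features. Those of 35 and 32 features, at 1.86 and -2.93, differed between DBS and naive by only -0.084 and 0.014. A dye effect could contribute and stays open. A control-like set of 13 features was 0.367 higher in DBS than in naive (-0.74 ± 0.15, n = 4, against -1.10 ± 0.11, n = 3, exact two-sided permutation p = 0.0571, 0.171 adjusted over the 3 sets). Its sham level of -1.13 ± 0.09 (n = 4) did not lie in between and so did not follow the graded order. In DBS this set stood even further above sham than above naive, by more than the median size of 0.35 of the calls in DBS against sham. That gap to sham was not tested, and a dye effect could also bear on DBS against sham. A different share of thalamic or cortical tissue in the dissections may also contribute: DBS minus naive correlated at -0.204 with the sham profile against the pool over the 3694 changed features, and from -0.317 to -0.062 for single sham arrays, which does not decide it. A factor that differs from pool to pool inside the DBS and sham groups could contribute, on the evidence of 1 set picked for its wide range. With group means removed, this 10-feature set followed the position of all other features over the 11 arrays (Pearson r = 0.906, permutation p = 0.00572, and Spearman rho = 0.827, permutation p = 0.0144). Its r was 0.816 without sham replicate 1 and DBS replicate 4. The other 10-feature sets were not tested in this way. The relation rests on the 8 arrays of operated rats (r = 0.963, exact permutation p = 0.00521; rho = 0.905, exact permutation p = 0.0122; adjusted over both sets of arrays 0.00572 and 0.0144; r = 0.932 without DBS replicate 4 and sham replicate 4), as the set hardly varied among the 3 naive arrays (-3.13 to -3.03), which did not follow it. Such a factor could be biological, for example a response of varied strength to the operation and the stimulation, or technical, and the slides and dates that would part these are not given in the sources used here.

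The second pattern is that features sharing a gene name do not share their log ratios. Random noise between arrays cannot hide the likeness, since the lowest correlation between any pair of arrays over all features was 0.732. A bias of single probes that repeats on every array would not lower that value. Such a bias would largely cancel in DBS minus naive, where features of the same symbol correlated at -0.0038. Most features did not change between DBS and naive, which limits that check. A numbering shifted by a constant is argued against by 4000 shifts of up to 2000 places, whose highest correlation between features of the same symbol was 0.0617, and 644 rearrangements of the rows into grids reached at most 0.0629. A candidate explanation is that the annotation describes another array layout with control spots in the same places. Of the 80 features in the 3 control-like sets, 0 are listed in the annotation, which lists 54.2% of all features. These 80 are copies within 3 sets and not independent. The size limit of 13 features was set after the values were seen, just above a set of 12 with 9 listed members. The 0 may therefore partly restate that choice. Within each set of 9 to 12 repeated features, every listed member carries a different accession. The layout explanation remains a hypothesis, and no biological explanation was tested for this pattern.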
